A study of Caenorhabditis elegans with 161 samples.

How the data were processed

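Whole embryos of the nematode Caenorhabditis elegans were profiled in 20 strains at 7 stages. Per the labels, 19 of the strains are mutation-accumulation lines known by a number, and N2 is the laboratory reference strain of the species. Mutation-accumulation lines are kept through severe bottlenecks so that new mutations persist with little selection. Stages were 0, 60, 180, 270, 440, 650 and 830 min after the 4-cell stage, and each library held a pool of 10 embryos. A second set of 21 libraries repeated strain 522 with 3 libraries at each of 7 time points. The time field of 18 of these 21 libraries contradicts the time point in their titles, so they were grouped by title, as the letters A to G. Where the repeats were set beside the stages, A to G were matched in order to the stages from 0 to 830 min. Their time field was not used. Nothing in the labels says that pools came from separate cultures, so every p-value measures the spread between these samples, which may be technical. Each stage group of 20 holds 1 library per strain, and the strains are its replicates.

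RNA with a polyA tail was sequenced by CEL-Seq, which counts the 3' ends of transcripts after barcoding and linear amplification, per the labels. The deposited values are raw counts per gene, as whole numbers, and per the submitters' processing notes the reads were handled with CASAVA 1.8 and aligned with Bowtie2 2.1.0. The counting program, the genome build, the annotation and the use of strand are not given in the sources used here, and no coordinates are printed. No molecular identifiers are stated, so intervals and floors cover counting error only. The table holds 20687 genes. Gene symbols were taken from the RefSeq annotation of the species, in which 20063 identifiers matched a locus tag and 624 did not, and 170 of the identifiers start with linc. Genes without a symbol are named by identifier. Rows that name no gene were left out of totals and tests. In the 29 library columns that list them, reads that did not align made up 38.8% to 70.2% of reads, and 17.8% to 47.7% of aligned reads fell in no feature. The 92 spike-in rows hold 0 in each library. Near-identical paralogs, such as skr-7, skr-8, skr-10 and skr-14, pes-2.1 and pes-2.2, cyb-2.1 and cyb-2.2, fkh-3 and fkh-4, the abu and vit genes, histones and some ribosomal proteins, can share reads, and their separate values are uncertain.

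A table of reruns repeats 8 of the strain libraries with identical counts, and these were used once. Of 7 further columns named as copies of strain 522, 1 equals its namesake, 5 equal a repeat library and one named for 180 min equals the 650 min library of strain 522. None of these columns entered a test. Total counts per strain library ran from 5653 to 525902 with a median of 57199, and those of the repeats from 58543 to 623958 with a median of 219346. In 4 strain libraries the total lay under 14299.75, 0.25 of the median. As a check of labels, each library was correlated with the stage means over 4131 genes with itself left out. All 140 strain libraries matched their own stage best, with a lowest r of 0.602, and so did the 21 repeats, with a lowest r of 0.866.

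Adjacent stages were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr), fitted to the libraries of both groups alone. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Tests were two-sided unless stated. Positive log2 fold changes mean higher at the later stage. In comparisons, CPM values are means, TMM-scaled and relative to the counts on the genes tested, given with the SD over the 20 strains. In the plot of levels by stage, CPM is relative to all gene counts. For a gene with 0 counts in a group, a fold was set against a floor of 3 counts over the 3 libraries of the group. On simulated data for 270 to 440 min (1151 genes), the test recovered 87% of genes changed 2-fold and 100% of those changed 4-fold, and called 0.736% of unchanged genes. For D to E in the repeats (6247 genes) the shares were 15%, 80% and 0.0496%.

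The strains pair the libraries across stages. Over 2970 genes, the median correlation of deviations from the stage means was 0.0936 to 0.150 between libraries of the same strain, against -0.0233 to -0.00731 between strains. A fit with strain as a block was an alternative. The 23 gene lists were set before the data were examined, as were the design of each test and the rule for named genes. That rule takes, per comparison, the 5 largest rises and 5 largest falls among called genes that reached a mean of 50 CPM in the higher stage and moved alike in at least 19 strains. It adds 2 to 4 members of each list described, those with the smallest p of the list. For strain effects it takes the 15 genes with the smallest p, and 4 genes in each of the 5 strains with the most shifted genes. Lists were tested against the other genes with camera (limma 3.58.1, correlation preset at 0.01, lists of at least 3 measured genes, 60 tests adjusted together). The list of 12 mitochondrially encoded genes matched 0 names, and 12 genes whose identifiers start with MTCE were used in its place, a choice made after the table was seen.

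Spread between strains was measured in 136 libraries thinned to 14368 counts. It is the root mean square over genes of the deviation of log2(CPM + 1) from the median of the other strains, over the 28 genes with a mean of at least 10 thinned counts at every stage. Each strain's log2 ratio of a stage to the mean of its other stages was tested by a paired sign-flip permutation test with 100000 resamples, adjusted over the 7 stages. The biological coefficient of variation (BCV), which leaves out counting noise, was estimated by edgeR with jackknife intervals over strains. Genes were those that passed the filter in the strain libraries of a stage, and the same genes were used in the repeats. Tested on simulated data, it returned 0.299 for 0.3 and 0.604 for 0.6. The variance of each list was ranked among 10000 random lists matched on mean expression. Strain effects were tested over 2970 genes in 140 libraries by edgeR with stage as a covariate, as an F test over strains and as each strain against the mean of the other 19. With a simulated shift in strain 530, the F test recovered 23% of genes shifted 2-fold and 83% of those shifted 4-fold, and the test of the single strain 65% and 96%, with 0.866% and 0.361% of unchanged genes called. Timing offsets are projections of each library's deviation on the direction from the previous to the next stage, in minutes.

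Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the block, and fits without N2, without shallow libraries or without single repeats, with others for the spread and strain tests. Chosen after seeing the data were fits without the 8 rerun libraries, without 6 late libraries that hold 0 min transcripts, and within the first 6 or last 14 strains of the sample numbering. Permutations and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.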

Results

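Transcripts were counted in 140 pools of 10 whole embryos, from 20 strains at 7 stages between 0 and 830 min after the 4-cell stage, and in 21 repeat pools of strain 522. Each stage group held 20 libraries, 1 per strain. The median total count per library was 51106.5 at 0 min, 55656 at 60 min, 53079 at 180 min, 54351 at 270 min, 57953.5 at 440 min, 79484.5 at 650 min and 50644.5 at 830 min. Single libraries ran from 5653 to 525902 counts. At this depth between 1011 and 1344 genes could be tested per pair of adjacent stages, so each comparison covers the more abundant transcripts. The design asks how gene expression changes along the embryonic time course and whether variation between strains depends on the stage.

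Between 0 and 60 min, transcripts of the egg gave way to the first transcripts of the embryonic genome. The largest rises were in ZK899.6 (2.33 ± 9.12 to 773 ± 344 CPM, mean ± SD, n = 20), sdz-9, a gene named for its dependence on the transcription factor SKN-1, the near-identical pair pes-2.2 and pes-2.1, and skr-8, a relative of the ubiquitin ligase subunit Skp1. Their log2 fold changes were 7.57 ± 0.38 (SE), 7.22 ± 0.36, 7.21 ± 0.26, 7.08 ± 0.25 and 6.96 ± 0.28, with a rise in 20 of 20 strains each. The largest falls were in era-1 (863 ± 244 to 68 ± 90.2 CPM, log2 fold change -3.24 ± 0.24), T21C9.13 (-2.96 ± 0.32), C14B1.2 (-2.90 ± 0.20), the glycolytic enzyme enol-1 (-2.86 ± 0.17, from 3936 to 519 CPM) and K06B9.2 (-2.81 ± 0.20), each in 20 of 20 strains. Of 19 measured maternal germline and egg genes, 16 fell and 0 rose, among them the RNA-binding proteins oma-2 (-2.54 ± 0.15), mex-5 (-2.27 ± 0.15), puf-5 (-2.29 ± 0.15) and spn-4 (-2.23 ± 0.15). All 3 measured genes of early zygotic specification rose, namely pes-10 (5.95 ± 0.27), vet-6 (6.80 ± 0.28) and vet-1 (5.44 ± 0.29). The 4 measured eggshell genes all fell, including the chondroitin proteoglycans cpg-1 (-2.71 ± 0.20) and cpg-2 (-2.46 ± 0.18). Of 5 Argonaute and small RNA genes 3 fell, the Argonautes hrde-1 (-2.12 ± 0.18) and wago-1 (-1.89 ± 0.18) and the Piwi protein prg-1 (-1.73 ± 0.17). Of 54 ribosomal protein genes 8 rose and 0 fell, with a list median of 0.83. Examples are rps-13 (1.47 ± 0.22) and rps-16 (1.34 ± 0.21), while rpl-7A (0.99 ± 0.14) and rps-29 (0.97 ± 0.15) missed 2-fold. Of 23 cell cycle genes 3 fell, the kinase air-1 (-1.40 ± 0.12) and the B-type cyclins cyb-2.2 (-1.60 ± 0.15) and cyb-2.1 (-1.70 ± 0.16), and cyb-1 stood at 0.77 ± 0.10. The linker histone his-24 (2.77 ± 0.27) and his-72 (1.13 ± 0.12) rose and his-74 fell (-1.54 ± 0.20) among 4 histones. Of 5 chaperones hsp-1 fell (-1.61 ± 0.15), and hsp-3 rose by 1.07 ± 0.13, a call lost with RLE scaling (0.99) and DESeq2 (0.99). Of 3 homeodomain genes 1 fell, the caudal relative pal-1 (-1.15 ± 0.17, and -0.99 with no filter, which ends the call), and the 1 measured F-box A gene, fbxa-215, fell (-1.26 ± 0.17). None of the 3 C-type lectins, 2 muscle genes and 11 mitochondrial identifiers measured was called.

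Of 1344 genes tested between 0 and 60 min, 133 rose and 295 fell by edgeR, 428 in all, and the largest adjusted p among the genes called above was 8.93e-08. Against the other genes, the fall of the maternal list held with the preset correlation (camera adjusted p = 2.02e-09) and with an estimated one (adjusted p = 0.0481). The zygotic list (adjusted p = 3.55e-04), the ribosomal list (1.06e-05) and the eggshell list (0.00397) passed only with the preset, with adjusted p = 0.0852, 0.349 and 0.161 with an estimated correlation. Without a filter on low counts 3402 genes were called, and within the last 14 strains 253.

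Between 60 and 180 min several transcripts that had risen before, such as ZK899.6, pes-10, vet-6 and vet-1, fell. Most of the measured homeodomain and ribosomal protein genes rose. The largest rises were in the NK2-type homeobox gene ceh-27 (5.30 ± 23.7 to 429 ± 98.6 CPM, log2 fold change 5.91 ± 0.39), F43G6.4 (5.70 ± 0.28), the bZIP gene zip-8 (5.57 ± 0.27, from 38.7 to 2067 CPM), the proneural gene hlh-14 (5.20 ± 0.27) and gmap-1 (4.61 ± 0.25). The largest falls were in C05D12.4 (-7.41 ± 0.31, from 521 to 0.684 CPM), the forkhead genes fkh-3 (-7.27 ± 0.34) and fkh-4 (-6.59 ± 0.29), K08H2.2 (-7.0 ± 0.33) and ZK899.6 (-6.69 ± 0.34). Each moved alike in 20 of 20 strains. Of 7 measured homeodomain genes 5 rose and 0 fell, led by the Iroquois gene irx-1 (4.52 ± 0.25), ceh-27, the Pbx relative ceh-20 (2.77 ± 0.22) and ceh-13 (2.41 ± 0.25), which is also the 1 Hox gene measured. Homeodomain genes are known to have been examined in the study, so this count is not independent evidence of their direction. Of 10 maternal genes 9 fell, such as oma-1 (-4.17 ± 0.23), ify-1 (-2.2 ± 0.14) and mex-1 (-3.23 ± 0.24). Among 5 early zygotic genes pes-10 (-6.52 ± 0.31), vet-6 (-4.30 ± 0.24) and vet-1 (-4.90 ± 0.27) fell, while the epidermal GATA factor elt-1 rose (3.53 ± 0.21) with 1 other. Of 7 epidermal genes 4 rose, including the netrin receptor unc-5 (3.57 ± 0.24), the zinc finger gene lin-26 (2.27 ± 0.20) and the spectrin spc-1 (1.96 ± 0.17). All 5 collagen and cuticle genes rose, such as sym-1 (4.37 ± 0.28), noah-1 (3.51 ± 0.26) and dpy-14 (2.68 ± 0.20). The muscle regulator unc-120 (3.84 ± 0.25) rose, 1 of 5 muscle genes, and so did the pharyngeal FoxA factor pha-4 (3.68 ± 0.24), the 1 pharynx gene measured. Of 74 ribosomal protein genes 58 rose and 0 fell (list median 1.29), led by rpl-11.2 (2.54 ± 0.17), rpl-23A.1 (2.36 ± 0.17) and rps-16 (1.93 ± 0.14). Of 23 cell cycle genes 5 fell, among them the ribonucleotide reductase subunit rnr-2 (-2.19 ± 0.11), cyb-1 (-1.15 ± 0.10) and the DNA clamp pcn-1 (-1.13 ± 0.12). Among 5 C-type lectins clec-91 (-5.33 ± 0.24) and clec-88 (-4.56 ± 0.21) fell with 1 more, and clec-266 rose (3.99 ± 0.18) with 1 more. Of 4 chaperones sip-1 fell (-4.17 ± 0.21) and hsp-3 rose (1.01 ± 0.11, a call lost without the filter at 0.93 and without N2 at 0.99). The histone his-24 rose (3.10 ± 0.21), 1 of 3, the Argonaute ergo-1 fell (-1.66 ± 0.19), 1 of 2, and of 2 eggshell genes the chitinase cht-1 rose (3.55 ± 0.18) and cpg-1 fell (-2.56 ± 0.31).

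Of 1330 genes tested between 60 and 180 min, 307 rose and 296 fell, and the largest adjusted p among the genes named was 7.92e-11 by edgeR. The tests of the homeodomain (camera adjusted p = 0.0209), maternal (0.00208), ribosomal (8.86e-14), epidermal (0.0189) and collagen (0.00497) lists passed with the preset correlation. With an estimated correlation none held, at adjusted p = 0.182, 0.161, 0.170, 0.161 and 0.176. The early zygotic list passed with neither (adjusted p = 0.455 and 0.536). Without a filter 4080 genes were called, and within the last 14 strains 394, against 603 in all 20.

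Between 180 and 270 min, the middle of the course, fewer of the measured genes were called than in the other comparisons. The intervals between stages differ in length, and the counts were not scaled to it. The bZIP gene ces-2 rose most (18.8 ± 39.8 to 1796 ± 502 CPM, log2 fold change 6.64 ± 0.28), followed by the claudin-like nsy-4 (5.35 ± 0.32), the cuticlin-like cutl-16 (5.09 ± 0.29) and cutl-2 (4.84 ± 0.21) and the insulin-like ins-2 (4.86 ± 0.30). The Skp1-related genes skr-7 (-4.29 ± 0.22, from 2713 to 118 CPM), skr-8 (-3.94 ± 0.28), skr-14 (-3.91 ± 0.30) and skr-10 (-3.64 ± 0.30) and the gene B0281.5 (-3.99 ± 0.25) fell most, each in 20 of 20 strains. Of 21 cell cycle genes 9 fell and 0 rose, including the helicase subunits mcm-2 (-3.28 ± 0.22) and mcm-7 (-1.62 ± 0.12), pcn-1 (-1.93 ± 0.15) and rnr-1 (-2.30 ± 0.18). Of 10 collagen and cuticle genes 9 rose, such as dpy-14 (2.26 ± 0.10), dpy-17 (2.60 ± 0.13), sqt-3 (2.86 ± 0.14) and dpy-10 (4.25 ± 0.25). Among 14 epidermal genes the apical junction genes ajm-1 (3.79 ± 0.25) and dlg-1 (1.67 ± 0.16) and the spectrin sma-1 (1.47 ± 0.18) rose, 5 in all, and elt-1 fell (-1.41 ± 0.17). None of 10 homeodomain genes was called, with values of 0.75 ± 0.13 for unc-62, 0.69 ± 0.15 for ceh-32 and 0.54 ± 0.12 for ceh-20. The muscle actin act-4 (1.38 ± 0.13), 1 of 7 muscle genes, the gut protease cpl-1 (1.34 ± 0.17), 1 of 2 gut genes, and rps-27A (1.15 ± 0.11), 1 of 74 ribosomal genes, rose. The hatching enzyme hch-1 rose (4.12 ± 0.20) and cht-1 fell (-2.32 ± 0.17), among 3 eggshell genes whose median was -0.15 while the test of the list pointed upward, without passing. Of 2 C-type lectins clec-196 fell (-1.19 ± 0.14).

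Of 1206 genes tested between 180 and 270 min, 92 rose and 87 fell, and the largest adjusted p among the called genes named was 1.29e-09 by edgeR. The falls of the cell cycle list (camera adjusted p = 3.07e-09) and the rise of the collagen list (1.26e-10) held with an estimated correlation, at adjusted p = 2.07e-04 and 0.00134. The ribosomal (4.55e-17), muscle (0.0255) and epidermal (0.0432) lists passed only with the preset, with adjusted p = 0.150, 0.253 and 0.418 with an estimated correlation, and the epidermal call was also lost with strain as a block (adjusted p = 0.0506). Without a filter 1978 genes were called, and among them 26 of 93 homeodomain genes rose and 4 fell.

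Between 270 and 440 min, most of the measured muscle genes and of the collagen and cuticle genes rose, and the measured cell cycle genes fell. The largest rises were in F01D5.6 (7.15 ± 20.3 to 1144 ± 824 CPM, log2 fold change 5.94 ± 0.41), F32A5.4 (5.50 ± 0.32), the hedgehog-related wrt-2 (5.20 ± 0.33), chtb-1 (5.04 ± 0.26) and the bZIP gene atf-8 (4.97 ± 0.26). The largest falls were in ins-2 (-7.57 ± 0.42, from 669 to 1.19 CPM), ces-2 (-6.91 ± 0.27), cutl-2 (-6.22 ± 0.23), dsl-3, of the family of Notch ligands (-6.09 ± 0.31), and cpg-20 (-5.62 ± 0.30), each in 20 of 20 strains. Of 24 muscle genes 18 rose and 0 fell, with a median of 3.01, such as the vinculin deb-1 (4.03 ± 0.24), the troponin tni-1 (3.38 ± 0.19), clik-1 (4.25 ± 0.23) and dim-1 (3.41 ± 0.17). All 9 measured cell cycle genes fell, including the mitotic kinases plk-1 (-3.22 ± 0.21) and cdk-1 (-2.67 ± 0.18), mcm-7 (-3.18 ± 0.22) and the cytokinesis gene cyk-4 (-3.02 ± 0.23). Of 15 collagen and cuticle genes 9 rose and 2 fell. The patched-related ptr-4 (4.48 ± 0.29), the lipocalin-related lpr-3 (2.78 ± 0.17) and dpy-2 (2.2 ± 0.14) were among the rises and the fibrillin-like fbn-1 (-3.54 ± 0.19) among the falls. Among 15 epidermal genes vab-10 (1.15 ± 0.15), mel-11 (1.27 ± 0.17) and 1 other rose. The gut genes ifb-2, an intermediate filament (3.21 ± 0.23), and act-5, the actin of microvilli (1.74 ± 0.21), rose, 2 of 5. Of 8 homeodomain genes ceh-27 (-2.24 ± 0.17) and the Hox gene ceh-13 (-1.27 ± 0.19) fell, and ceh-20 (-0.76) and ceh-44 (0.98) were not called. The cilium regulator daf-19 rose (1.70 ± 0.18), pha-4 fell (-1.48 ± 0.18) and the pharyngeal troponin tni-4 rose (2.62 ± 0.35). Of 7 chaperones hsp-12.2 (4.47 ± 0.24), hsp-12.1 (3.29) and hsp-25 (2.62 ± 0.18) rose and hsp-3 fell (-1.07 ± 0.10, a call lost without the filter at -0.83 and without N2), and of 5 histones 3 rose, among them his-35 (3.17 ± 0.23), and his-24 fell (-3.0 ± 0.14). Both measured C-type lectins fell, clec-196 (-4.66 ± 0.24) and clec-266 (-3.41 ± 0.18), as did cht-1 (-4.32 ± 0.30), 1 of 3 eggshell genes. None of 74 ribosomal genes was called (median 0.60).

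Of 1151 genes tested between 270 and 440 min, 237 rose and 226 fell, and the largest adjusted p among the called genes named was 4.64e-08 by edgeR. The cell cycle (camera adjusted p = 1.59e-04), muscle (6.19e-07), ribosomal (2.24e-06) and collagen (0.0360) lists passed with the preset correlation, and none held with an estimated correlation, at adjusted p = 0.161, 0.161, 0.450 and 0.349. Without a filter 5051 genes were called, among them 30 rises in 32 cilium genes, and 22 rises and 23 falls in 96 homeodomain genes.

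Between 440 and 650 min, most measured genes of differentiated gut, pharynx and neurons rose and most genes of epidermal morphogenesis and the embryonic cuticle fell. The largest rises were in W08E12.6 (0.889 ± 2.97 to 1405 ± 592 CPM, log2 fold change 8.76 ± 0.37), the ligand-gated channel gene lgc-21 (7.88 ± 0.39), the collagen col-104 (7.54 ± 0.35), pqn-74 (7.28 ± 0.32) and ZK662.2 (7.17 ± 0.28). The largest falls were in T03G6.1 (-7.16 ± 0.29), C06E7.88 (-7.04 ± 0.41), atf-8 (-6.98 ± 0.25), the lipocalin-related lpr-5 (-6.93 ± 0.29, from 1634 to 12.64 CPM) and the collagen dpy-3 (-6.84 ± 0.28), each in 20 of 20 strains. Of 13 gut genes 8 rose and 1 fell, among them the aspartyl proteases asp-5 (4.93 ± 0.18) and asp-1 (3.77 ± 0.16), the filament gene ifc-2 (4.88 ± 0.28) and the proton pump subunit vha-6 (3.70 ± 0.25). Of 8 pharynx genes 7 rose, including the pharyngeal myosins myo-2 (5.86 ± 0.27) and myo-1 (5.42 ± 0.26), abu-11 (6.97 ± 0.32) and abu-14 (4.43 ± 0.20). Of 10 neuronal genes 9 rose, such as the synaptotagmin snt-1 (4.57 ± 0.25), the vesicle protein rab-3 (3.08 ± 0.18), ida-1 (2.75 ± 0.22) and the carboxypeptidase egl-21 (2.29 ± 0.19). Of 28 muscle genes 11 rose and 1 fell, with rises in the troponin tnt-2 (3.89 ± 0.26), unc-87 (2.68 ± 0.17) and mlc-1 (1.89 ± 0.14). Of 16 epidermal genes 10 fell and 1 rose. Of these sma-1 (-3.0 ± 0.23) and the alpha-catenin hmp-1 (-2.25 ± 0.18) fell, and mup-4 rose (2.31 ± 0.17). Of 16 collagen and cuticle genes 13 fell and 2 rose, with falls in lpr-3 (-6.65 ± 0.26), dpy-3, dpy-2 (-5.70 ± 0.24) and noah-1 (-5.47 ± 0.24). Of 6 homeodomain genes ceh-20 (-1.58 ± 0.22) and ceh-44 (-1.40 ± 0.20) fell. Falls were also called for daf-19 (-1.41 ± 0.18), the 1 cilium gene measured, hch-1 (-5.04 ± 0.34), the Argonaute alg-1 (-1.44 ± 0.21) and his-24 (-1.24 ± 0.20), 1 of 5 histones. Of 8 chaperones hsp-12.1 fell (-4.20 ± 0.26) and the mitochondrial hsp-60 rose (1.21 ± 0.13), and the list median was 0.06 while the test pointed downward, without passing. Of 2 C-type lectins clec-63 rose (4.85 ± 0.30) and clec-180 fell (-5.16 ± 0.32).

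Of 1231 genes tested between 440 and 650 min, 257 rose and 286 fell, and the largest adjusted p among the genes named was 4.95e-07 by edgeR. The collagen (camera adjusted p = 2.01e-05), pharynx (3.81e-04), neuronal (8.17e-04), gut (0.0183), muscle (0.0260), epidermal (0.0320) and ribosomal (0.00409) lists passed with the preset. With an estimated correlation none held, at adjusted p = 0.0852, 0.0963, 0.161, 0.182, 0.450, 0.381 and 0.634. Without a filter 5120 genes were called, and 16 of 32 cilium genes fell and 1 rose.

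Between 650 and 830 min, the end of the course, 3 abu genes and the collagens col-54, col-14 and sqt-3 fell, while the collagens col-147, col-12 and col-13 rose. The largest rises were in C53B7.3 (0.849 ± 3.80 to 426 ± 198 CPM, log2 fold change 7.38 ± 0.40), marg-1 (7.02 ± 0.35), the collagen col-147 (6.89 ± 0.28, from 7.75 to 1324 CPM), fipr-1 (6.43 ± 0.35) and ZC116.1 (6.32 ± 0.35, in 19 of 20 strains). The largest falls were in D2092.8 (-7.50 ± 0.39), W08E12.6 (-7.12 ± 0.40), abu-14 (-6.87 ± 0.27, from 3638 to 34.5 CPM), the collagen col-54 (-6.59 ± 0.37) and the chitinase cht-5 (-6.57 ± 0.29). Of 10 pharynx genes 3 fell, abu-14, abu-11 (-5.79 ± 0.27) and abu-10 (-4.54 ± 0.46), and marg-1 rose. The median of that list was 0.20 and its test pointed downward, without passing. Of 6 collagen and cuticle genes col-14 (-5.31 ± 0.32), sqt-3 (-5.26 ± 0.32) and 1 other fell, and col-12 (1.99 ± 0.28) and col-13 (2.13 ± 0.30) rose. The homeodomain gene dve-1 fell (-2.24 ± 0.18), 1 of 2 measured. Of 29 muscle genes the perlecan unc-52 fell (-1.15 ± 0.12) and tnt-2 rose (1.20 ± 0.14), and of 11 neuronal genes the convertase egl-3 rose by 1.07 ± 0.15, a call lost without the 6 late libraries that hold 0 min transcripts (0.93) and in the last 14 strains (0.94). Of 11 gut genes ifc-2 rose (1.13 ± 0.14, and 0.93 in the last 14 strains, which ends the call). Rises were called for 2 of 3 C-type lectins, clec-209 (3.42 ± 0.30) and clec-63 (1.37 ± 0.14), for sdz-24 (3.36 ± 0.27), the 1 zygotic gene measured, and for the small heat shock gene hsp-17 (1.37 ± 0.24), 1 of 7 chaperones. None of 6 histones, 5 epidermal genes and 74 ribosomal genes was called. Of 1011 genes tested, 101 rose and 136 fell, and the largest adjusted p among the genes named was 2.78e-06 by edgeR. No list passed, with a lowest camera adjusted p of 0.0800 with the preset and 0.227 with an estimated correlation, and without a filter 2881 genes were called. In each comparison of adjacent stages, counts adjusted over the list alone were equal to those over all genes for each of the lists.

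**Figure D1:**
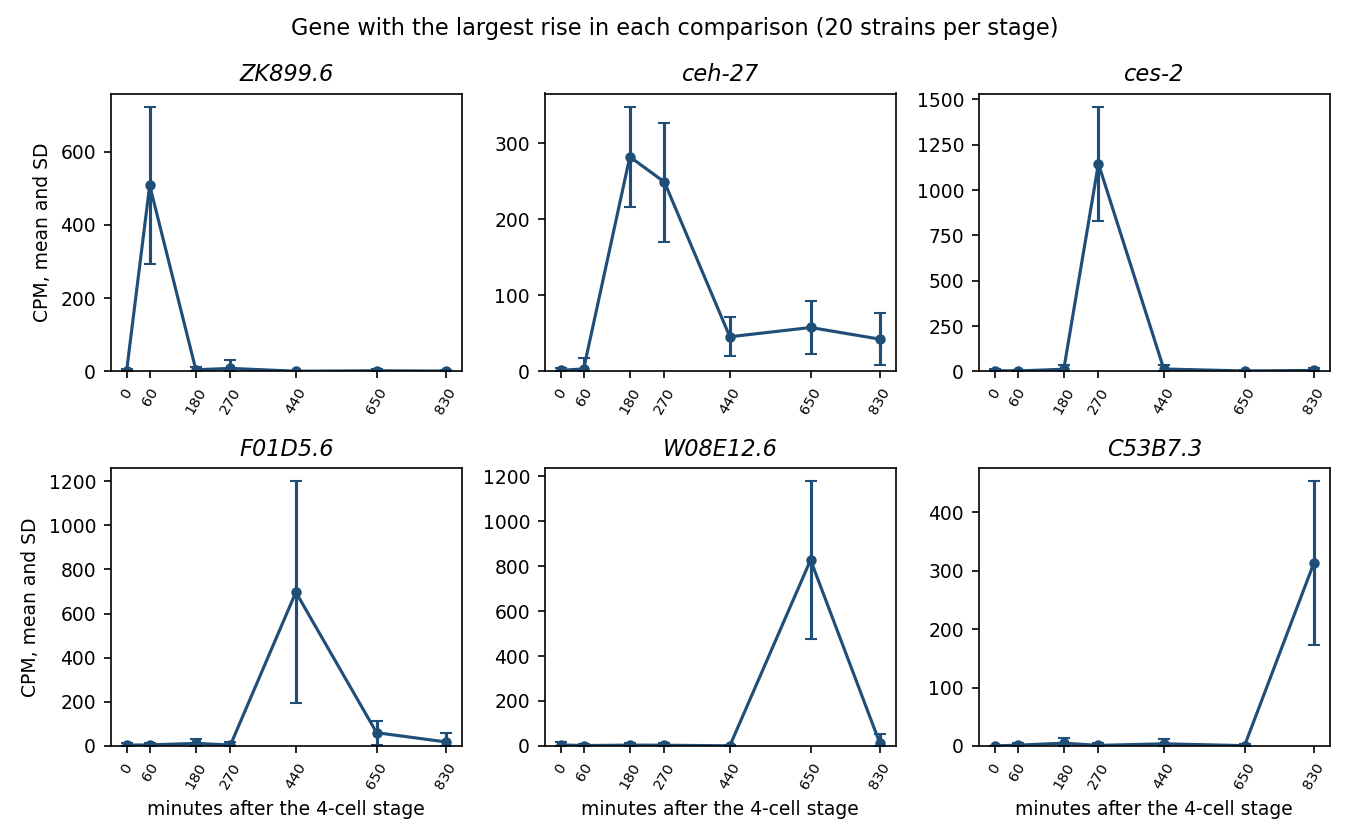
Mean CPM relative to all gene counts (y axis, linear, error bars SD over 20 strains) against minutes after the 4-cell stage (x axis) for the gene with the largest rise in each of the 6 comparisons. ZK899.6 averages 508 CPM at 60 min and 4.39 CPM at 180 min.

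**Figure D2:**
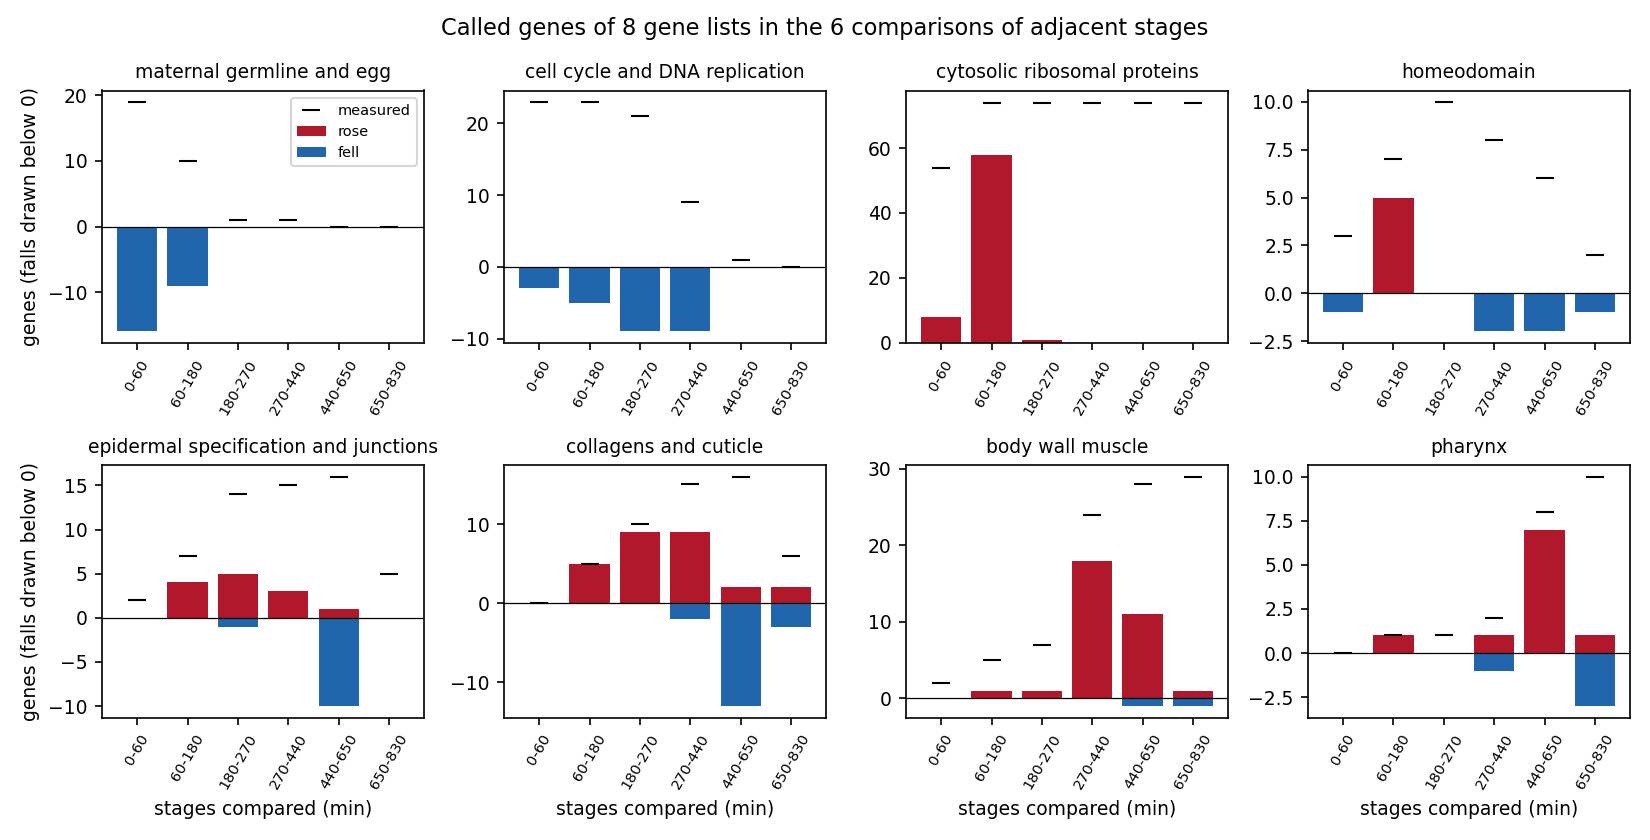
Numbers of called genes (y axis, rises above 0 and falls drawn below 0, dashes for genes measured) in 8 gene lists for the 6 pairs of adjacent stages (x axis). Of 19 measured maternal genes 16 fell between 0 and 60 min, and of 24 muscle genes 18 rose between 270 and 440 min.

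The repeats of strain 522, sequenced deeper, showed the same course and reached regulators of lower abundance. From A to B the zygotic genes pes-10 and vet-6 went from 0 counts to 1075 and 761 CPM, at least 216-fold and 153-fold above a floor of 3 counts over the 3 libraries, and ceh-51 and the proneural gene ngn-1 from 0 counts to 134 and 74.6 CPM. The homeodomain genes ceh-49 (log2 fold change 2.83 ± 0.29) and ceh-39 (2.08 ± 0.23), the Hox gene ceh-13 (5.26 ± 0.72) and the proneural gene hlh-3 (4.44 ± 0.55) rose, daf-19 fell (-2.43 ± 0.46), and 26 of 30 maternal genes fell, such as puf-11 (-2.70 ± 0.25). From B to C the homeodomain genes irx-1 (7.44 ± 0.39), nob-1 (6.27 ± 0.48) and ceh-37 (5.81 ± 0.46) rose, ceh-27 went from 0 counts to 309 CPM, and 55 of 75 ribosomal genes rose and 1 fell. From C to D the neuronal regulators egl-46 and unc-3 went from 0 counts to 287 and 116 CPM, lin-11 to 109 CPM, and pros-1 (6.03 ± 0.58), ttx-1 (4.44 ± 0.46) and lin-39 (1.72 ± 0.34) rose, while nob-1 fell (-1.49 ± 0.26). From D to E, 13 of 14 cilium genes rose and 0 fell, such as bbs-9 (5.04 ± 0.44), che-3 (4.83 ± 0.52) and dyf-1 (3.97 ± 0.41). Of 25 neuronal genes 14 rose and 5 fell, with rises in the synaptic gene ric-4 (5.01 ± 0.30) and the kinesin unc-104 (6.28 ± 0.53) and a fall in ngn-1 (-6.88 ± 0.54). From E to F, 11 of 13 cilium genes fell, such as dyf-7 (-4.65 ± 0.53) and dyf-5 (-2.80 ± 0.48), and 15 of 26 neuronal genes rose and 4 fell, with rises in snt-1 (3.49 ± 0.26) and rab-3 (2.80 ± 0.22). From F to G dve-1 fell (-2.24 ± 0.23) and ceh-62 rose (2.39 ± 0.45). Homeodomain genes rose and fell, respectively, in 9 and 1 of 16 measured from A to B, 11 and 7 of 23 from B to C, 7 and 2 of 25 from C to D, 9 and 13 of 43 from D to E, 2 and 10 of 29 from E to F and 1 and 1 of 24 from F to G. Counts for these lists were equal when adjusted over the list alone.

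Calls in the repeats (edgeR, n = 3 each) numbered 1845 of 4466 genes from A to B, 1367 of 2891 from B to C, 607 of 3198 from C to D, 3014 of 6247 from D to E, 2665 of 5709 from E to F and 1136 of 4798 from F to G. Across genes, which are not independent replicates, log2 fold changes in the repeats and in the 20 strains correlated with r = 0.963, 0.968, 0.920, 0.959, 0.960 and 0.936. Of the genes called in the strains and measured in the repeats, 428 of 428, 597 of 599, 178 of 179, 462 of 463, 539 of 543 and 237 of 237 moved in the same direction. The largest adjusted p among the genes called in the repeats above was 0.00100.

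Variation between strains was then compared between stages. Over the 28 genes measurable at all 7 stages after thinning, no stage differed from the others beyond the adjustment for 7 tests (permutation test, two-sided). The mid-course stage, 270 min, had a log2 ratio of spread to the other stages of -0.18 ± 0.38 (SD, n = 20), above 0 in 5 of 20 strains (p = 0.0512, adjusted p = 0.179). At the other stages the ratio was -0.08 at 0 min (adjusted p = 0.700), -0.21 at 60 min (0.123), 0.04 at 180 min (0.737), 0.19 at 440 min (0.321), -0.02 at 650 min (0.807) and -0.04 at 830 min (0.737), and none of 21 pairs of stages had an adjusted p under 0.343. Over the 218 to 267 genes measurable at each stage, an alternative gene set, 270 min (-0.16 ± 0.20, above 0 in 3 of 20 strains, adjusted p = 0.00150) and 830 min (-0.26 ± 0.26, 2 of 19 strains, adjusted p = 0.00215) lay below the other stages and 650 min above (0.47 ± 0.45, 16 of 20 strains, adjusted p = 0.00105) by the same permutation test. These gene sets differ between stages. The other stages against which 270 and 830 min were set include 650 min, with a median spread of 0.883. The median was 0.580 at 270 min, against 0.585 at 440 min and 0.589 at 60 min. Ratios were also below 0 at 0 min (-0.11), 60 min (-0.082), 180 min (-0.059) and 440 min (-0.055), without passing. With 1 minus the Spearman correlation as the measure, the common genes gave the opposite direction at 270 min (0.51, adjusted p = 0.00056) and a lower value at 650 min (-0.39, adjusted p = 0.00211, and -0.34 over the genes of each stage, adjusted p = 0.0148). By that measure over the common genes each of the 7 stages passed. Spread lay below the other stages at 0, 60, 650 and 830 min and above them at 180, 270 and 440 min. Counting noise alone gave a spread of 0.308 to 0.350 over the common genes, against observed medians of 0.555 to 0.700. Over the genes of each stage, spread in the thinned libraries still went with library totals at 60 min (r = 0.580, adjusted p = 0.0359 by permutation) and 830 min (r = 0.576, adjusted p = 0.0359). By the Spearman coefficient it did not (adjusted p = 0.370 and 0.745 by permutation), and without the 2 extreme libraries r was 0.494 and 0.139. The spread over the common genes was not set against totals.

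The BCV between strains, in which counting noise is modelled, was 0.25 at 0 min, 0.268 at 60 min, 0.260 at 180 min, 0.263 at 270 min, 0.286 at 440 min, 0.323 at 650 min and 0.276 at 830 min. In the repeats of strain 522 over the same genes it was 0.146, 0.153, 0.132, 0.158, 0.158, 0.193 and 0.188, so that variance between strains was 2.15 to 3.87 times that between repeats of 1 strain. Within the last 14 strains of the sample numbering it was 1.61 to 2.53 times, and leaving out 1 of the 3 repeats moved the ratio for all strains between 2.15 and 13.5 at 0 min, 1.66 and 15.1 at 60 min, 2.37 and 5.96 at 180 min, 1.68 and 30.4 at 270 min, 2.22 and 5.02 at 440 min, 1.69 and 12.5 at 650 min and 1.35 and 7.87 at 830 min. At 650 min the strain value exceeded the mean of the other stages by 0.0554 (95% jackknife interval 0.0248 to 0.0859) and at 0 min the difference was -0.0296 (-0.0567 to -0.00244), while 270 min did not stand apart (-0.0141, -0.0390 to 0.0107). Over 465 genes measured at all stages the BCV ran from 0.277 to 0.296, and none of 650 min (0.0106, -0.0192 to 0.0403), 0 min (0.0103, -0.0155 to 0.0362) and 270 min (-0.0126, -0.0385 to 0.0132) stood apart. In the first 6 strains of the numbering 650 min exceeded the other stages by 0.0439 (0.0103 to 0.0775) and in the last 14 by 0.0464 (-0.0281 to 0.121). In those first 6 strains 830 min exceeded the other stages by more, 0.0662 (0.0132 to 0.119), so 650 min was not the highest stage there.

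**Figure D3:**
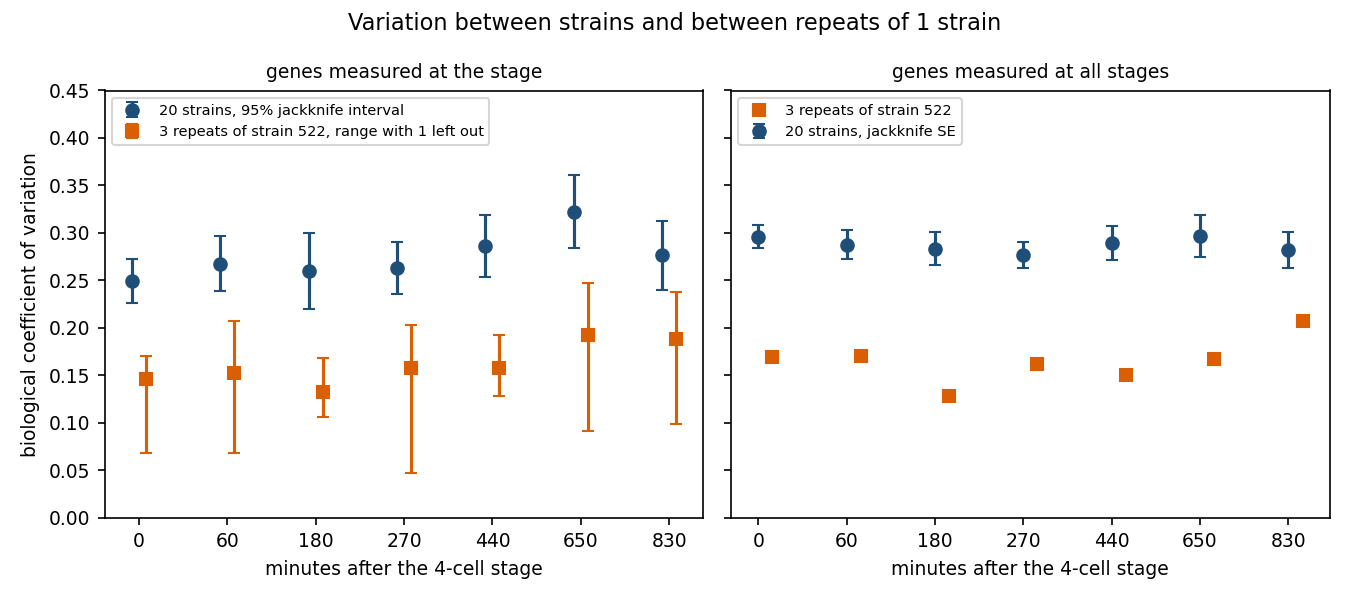
BCV (y axis) against minutes after the 4-cell stage (x axis) for genes measured at each stage (left, 95% jackknife intervals for 20 strains, range with 1 repeat left out for the repeats) and for 465 genes measured at all stages (right, jackknife SE). Strains lie between 0.25 and 0.323 on the left and between 0.277 and 0.296 on the right, above the repeats of strain 522.

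By gene group, ribosomal protein genes varied less between strains than genes of matched expression at 270 min (72 genes, median log2 ratio to the variance trend -0.36, percentile 1.12 of random lists) and at 650 min (74 genes, -0.71, percentile 0.04). Pharynx genes at 830 min varied more (4 genes, 0.89, percentile 98.97), but not with tagwise dispersion (6 genes, percentile 93.36), where the ribosomal genes stayed outside. These are the 3 of 26 combinations of list and stage outside the central 95%. Fewer than 3 homeodomain genes reached the floor of 10 thinned counts at each stage. With a floor of 5 counts, 3 homeodomain genes at 270 min had a median of -1.04 (percentile 6.76), which is not outside the central 95%.

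Differences between strains averaged over stages involved transcripts with MTCE identifiers, which match no symbol of the fixed mitochondrial list, and a range of nuclear genes. All 12 MTCE genes differed between strains and fill the first 12 places among the 15 genes with the smallest p. MTCE.11 led (F = 22.5, adjusted p = 2.35e-30), with a log2 shift of 1.51 in strain 570 and -1.62 in strain 529. They were followed by sel-9 (1.08 in strain 570, -0.90 in strain 536), ril-1 (0.97 in strain 550, -0.61 in strain 573) and nog-1 (0.63 in strain 566, -0.85 in N2). Among single strains, 550 had the most shifted genes, 300, led by the Argonaute wago-1 (1.86 ± 0.21, but 1.15 without the 6 late libraries that hold 0 min transcripts), cmt-1 (1.58 ± 0.19), MTCE.12 (1.27 ± 0.15) and MTCE.25 (1.19 ± 0.14). In N2, with 201 genes, MTCE.31 (1.47 ± 0.13), MTCE.3 (1.72 ± 0.16), MTCE.12 (1.59 ± 0.15) and MTCE.23 (1.35 ± 0.13) led. Strain 555, with 149, had MTCE.25 (1.31 ± 0.14), R107.5 (1.45 ± 0.19), MTCE.11 (1.13 ± 0.15) and F48F7.6 (1.32 ± 0.18). Strain 575, with 96, had the bZIP gene zip-2 (1.35 ± 0.18) besides MTCE.26 (1.08 ± 0.13), MTCE.23 (1.07 ± 0.14) and MTCE.31 (1.03 ± 0.13), calls lost with RLE scaling at 0.90, 0.89 and 0.87. Strain 570, with 86, had MTCE.11 (1.45 ± 0.15), T28B8.1 (1.49 ± 0.17), MTCE.25 (1.23 ± 0.15) and the fatty acid desaturase fat-2 (1.98 ± 0.25). The largest adjusted p among these shifts was 4.54e-09 by edgeR. Each was higher in 7 of 7 stages except zip-2 (5 of 7), fat-2 in strain 570 and MTCE.25 and MTCE.11 in strain 555 (6 of 7). These 5 strains are among the first 6 of the sample numbering, and the counts are against all other strains. Within the first 6 the counts were 27 for 550, 19 for N2, 25 for 555, 10 for 575 and 4 for 570, and of the 20 shifts named only those of wago-1 (1.25), zip-2 (1.33), T28B8.1 (1.14) and fat-2 (1.77) were called. MTCE.11 in strain 555 turned to -0.064 there. By list, a strain effect was called for 9 of 13 homeodomain genes, 1 of 1 Hox gene, 21 of 30 muscle genes, 18 of 29 cell cycle genes, 13 of 19 collagen and cuticle genes, 11 of 19 epidermal genes, 10 of 19 maternal genes, 7 of 12 neuronal genes, 5 of 13 gut genes, 5 of 10 pharynx genes, 10 of 13 chaperones, 7 of 9 histones, 5 of 5 vitellogenins, 4 of 9 Argonaute genes, 3 of 6 eggshell genes, 4 of 8 C-type lectins, 0 of 1 cilium gene and 38 of 75 ribosomal genes, of which 0 shifted 2-fold in a single strain. A strain effect was also called for 2 of 6 early zygotic genes and 1 of 1 F-box A gene. Over all genes tested it was called for 1829 of 2970 (61.6%), and the list counts come from the same fit of all 20 strains. No list was tested against that share. Adjusted over the list alone, the count was 22 for muscle, 11 for chaperones, 8 for histones and 5 for C-type lectins, and equal for the other lists.

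In all, 1829 of 2970 genes differed between strains, and 1037 combinations of gene and strain passed as shifted, 651 higher and 386 lower, in 694 genes. With limma-trend the balance turned, with 85 of 1074 higher. In strains 530 and 552 edgeR called 0 genes, with 214 and 354 at an unadjusted p under 0.05. The strain effect was called for 61.6% of the genes tested over all strains, for 2.67% of 4200 within the first 6 strains of the sample numbering and for 11.6% of 2285 (265 genes) within the last 14. Without a filter it was called for 4158.

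The MTCE share of counts followed the sample numbering. Its mean over 7 stages was 1.73% to 2.94% in the first 6 strains of the numbering (550, 570, 502, 555, N2 and 575; mean 2.1% ± 0.439 SD) and at most 1.36% in the other 14 (mean 0.943% ± 0.248). As a difference of mean log2 shares the step was 2.28-fold, the largest over all places to split the numbering (permutation p = 0.00201). In strain 522 it was 1.25%, and 0.793%, 0.840% and 0.802% in its 3 series of repeats.

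**Figure D4:**
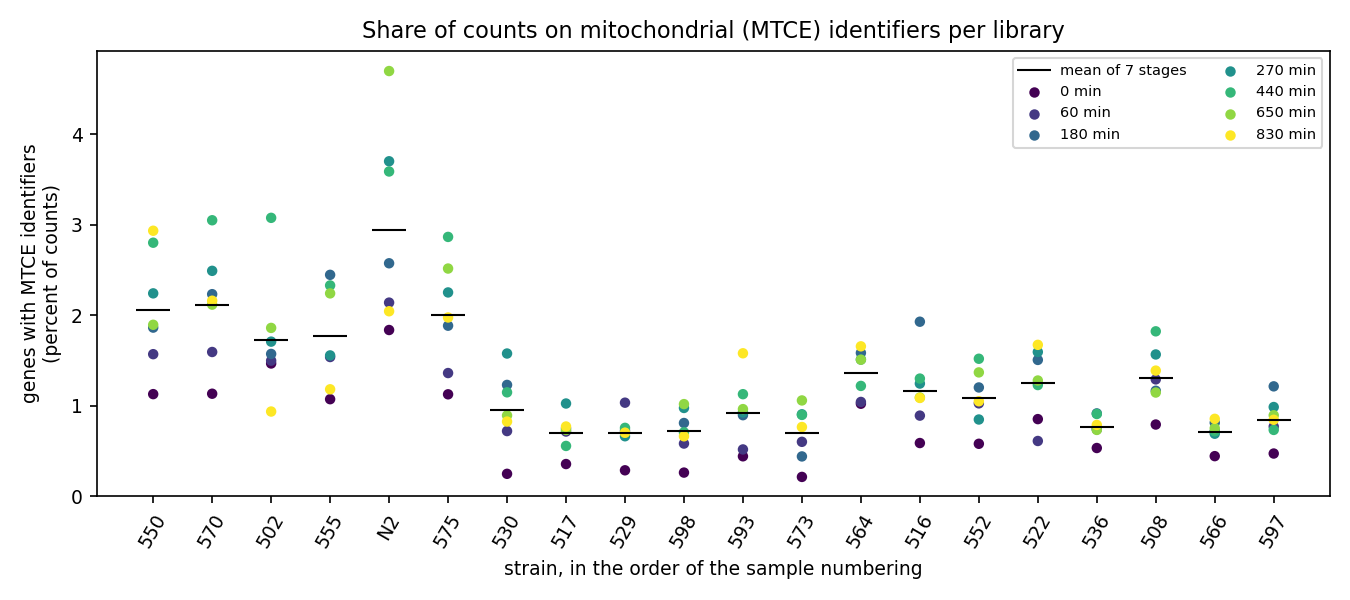
Share of counts on the 12 genes with MTCE identifiers (y axis, percent) for 20 strains in the order of the sample numbering (x axis), 1 point per stage, with the mean of 7 stages as a dash. The means of the first 6 strains lie between 1.73% and 2.94% and those of the others at or below 1.36%.

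Strains could run ahead of or behind the nominal stage. The SD of the strains' mean timing offsets was 13.4 min, not beyond that of strain labels permuted within stages (one-sided permutation p = 0.179). With 136 libraries thinned to 14368 counts it was 10.5 min and passed (p = 0.00465 by the same test). The 4 shallow libraries kept their lower totals there, so depth was not fully equal. The SD of single libraries ran from 9.52 min at 180 min to 59.1 min at 650 min. Offsets went with library totals at 4 of 7 stages (permutation tests adjusted over 7 stages). At 0 min r was 0.851 (p = 1e-05, the smallest possible, adjusted p = 7e-05) and the Spearman coefficient 0.857 (p = 1e-05, adjusted p = 7e-05), with r = 0.885 without the 2 extreme libraries, 0.853 in the first 6 strains and 0.944 in the last 14. At 60 min r was 0.511 (permutation p = 0.0233, adjusted p = 0.0407) and the Spearman coefficient 0.581 (p = 0.00831, adjusted p = 0.0145), with r = 0.528 without the 2 extremes, -0.421 in the first 6 strains and 0.842 in the last 14. At 650 min r was -0.789 (permutation p = 8e-05, adjusted p = 0.00028) and the Spearman coefficient -0.787 (p = 7e-05, adjusted p = 0.000245), with r = -0.735, -0.734 and -0.882 in the same order. At 830 min r was -0.624 (permutation p = 0.00291, adjusted p = 0.00679) and the Spearman coefficient -0.740 (p = 0.00039, adjusted p = 0.00091), with r = -0.903, -0.657 and -0.707. At 180, 270 and 440 min r was -0.264, 0.117 and -0.383 (permutation, adjusted p = 0.303, 0.622 and 0.136). The laboratory strain N2 had the second largest mean spread of the 20 strains, 0.773 against 0.619 ± 0.0958 in the others (exact permutation p = 0.2, two-sided, where the smallest one-sided p is 0.05). It ranked 1 without thinning and over the genes of each stage and 3 by 1 minus the Spearman correlation.

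In 6 of the 60 libraries from 440 min on, transcripts typical of 0 min stood above 5% of their 0 min level, against a median of 1.68%. The level was 22.2% in strain 550 at 650 min (95% exact Poisson interval 21.49% to 22.9%, 231 of 231 genes detected), 9.96% in strain 550 at 440 min (9.36% to 10.6%), 10.3% in strain 566 at 440 min (9.05% to 11.8%), 9.55% in N2 at 650 min (8.47% to 10.7%), 5.58% in strain 564 at 650 min (5.19% to 5.995%) and 5.54% in strain 555 at 650 min (5.17% to 5.93%). Detected were 205 of 231 genes in strain 550 at 440 min, 192 of 214 in 555, 181 of 236 in 564, 125 of 208 in N2 and 91 of 207 in 566. In strain 566 the median level over genes was 0%. The repeats reached at most 2.59%. Simulated from the pooled 650 min counts, these libraries included, the measure returned 4.3% with 0% of the 0 min profile mixed in and 13.4% with 10%. The 5% cut thus lies near the value for 0%. Without these 6 libraries 476, 516 and 256 genes were called at the last 3 comparisons.

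**Figure D5:**
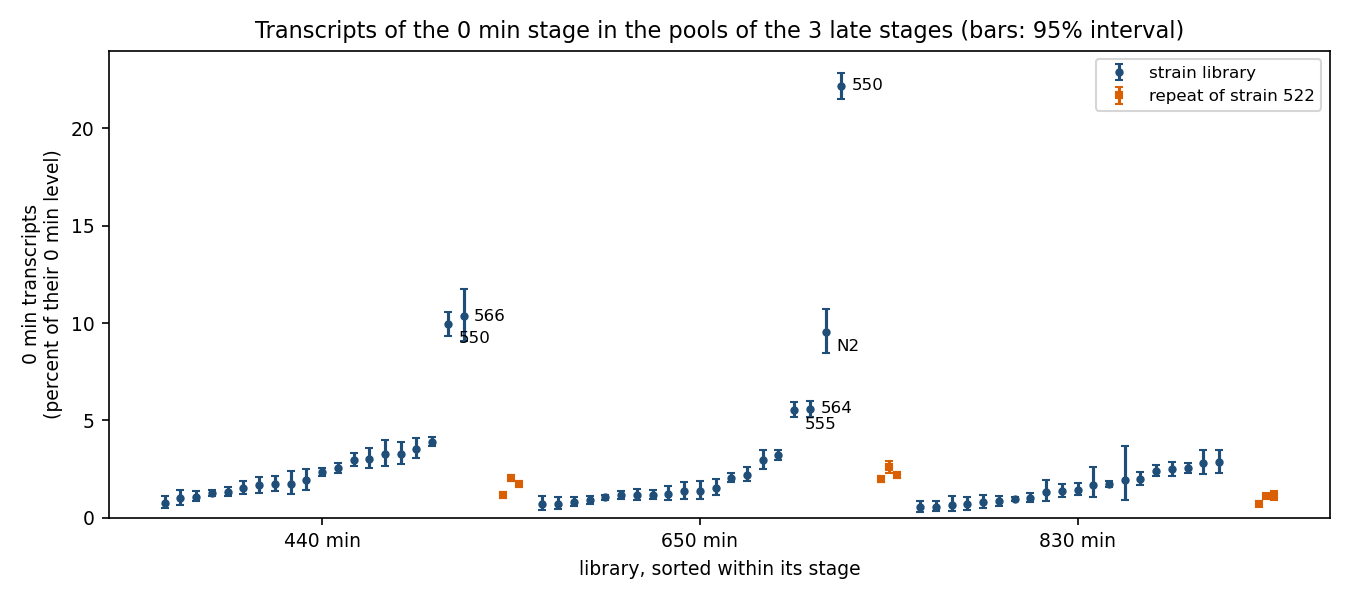
Level of 0 min transcripts in each late library, as a percent of their level at 0 min (y axis, 95% intervals), sorted within 440, 650 and 830 min (x axis), with the repeats of strain 522 beside the strains. Strain 550 at 650 min stands at 22.2% and the median of the 60 strain libraries is 1.68%.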

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

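The test of the interaction, the Spearman measure over the genes of each stage, the contrasts without the 6 late libraries, the shuffling within parts of the sample numbering and the tests of explanations in this part were chosen only after the results were seen. The stage comparisons, also over the genes of each stage, and the strain tests themselves were planned.

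Strain effects differed between early and late stages in 114 of 2970 genes by a test of the interaction itself (edgeR, adjusted p under 0.05, 438 at an unadjusted p under 0.05). The smallest p belonged to cyb-3, a B-type cyclin with a log2 shift of -1.64 in strain 529 at the 3 late stages and 0.27 at the 3 early ones. Next were cyb-1 (1.8 late and 0.02 early in strain 550), sip-1 (2.62 and -0.12 in strain 550), col-124 (-0.75 and 1.73 in strain 564), clec-87 (2.77 late in strain 550) and C41G7.7 (3.71 late in strain 597). Timing offsets at 650 min were 119.4 min in strain 529, 98.96 min in 597, -78.91 min in 550 and -13.98 min in 564. Whether pools ahead of or behind their nominal stage account for these shifts was not tested. Both sip-1 and clec-87 are among the 0 min transcripts and stood at 20.6% and 23.4% of their 0 min level in the 650 min library of strain 550. Without the 6 late libraries that hold such transcripts 58 genes were called (312 at an unadjusted p under 0.05), 55 of them among the 114, and clec-87 was not (adjusted p = 0.169). In strain 564, mup-2 (1.86) and cpn-3 (2.09) were high early as well. Transcripts typical of 650 min stood at 1.5%, 3.4% and 4.0% of their 650 min level in its libraries of 0, 60 and 180 min. The median of the early strain libraries was 1.2%. Whether such transcripts account for the early values of col-124, mup-2 and cpn-3 was not tested. Lower spread than at the other stages, over the genes of each stage, came out at 270 min (-0.16) and at 830 min (-0.26) by permutation tests of the difference. The other stages include the high value at 650 min. The median spread at 270 min (0.580) was close to that at 440 min (0.585) and 60 min (0.589). By 1 minus the Spearman correlation 270 min turned, to 0.15 over the same genes (adjusted p = 0.0379) and 0.51 over the common genes (adjusted p = 0.00056). The BCV between strains at 0 min lay apart from the other stages by -0.0296, by the jackknife interval of the contrast. Over the 465 genes measured at all stages that contrast turned to 0.0103 (-0.0155 to 0.0362), and without the 6 late libraries it was -0.0262 with an interval that reaches 0.

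Variation between strains at 650 min stood above the other stages over the genes of each stage, with a log2 ratio of spread of 0.47 and a BCV contrast of 0.0554 (0.0248 to 0.0859). By 1 minus the Spearman correlation it stood below, at -0.34 over the same genes and -0.39 over the common genes, where the root mean square gave -0.02. The genes that can be measured at 650 min may account for it, since the contrast over the 465 genes measured at all stages was 0.0106 with an interval that spans 0. The late libraries with 0 min transcripts are argued against for the ratio of spread, which was 0.47 without them (adjusted p = 0.00602). For the BCV they stay open, as the contrast without them was 0.0411 (-0.0117 to 0.0939), below the full value by less than the spread. Variation between libraries of 1 strain also stays open. The ratio of strain to repeat variance at 650 min was 2.80, within the 2.15 to 3.87 of the other stages, but leaving out 1 of the 3 repeats moved it between 1.69 and 12.5. Differences between the strains that grow at this stage remain a further explanation, which these data cannot separate from those.

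The number of changed genes exceeded that of other splits of the same libraries in each comparison of adjacent stages. Only 1 of 100 splits, the real one, gave as many, and the highest of the others was 108 against 428, 229 against 603, 64 against 179, 267 against 463, 387 against 543 and 101 against 237, so chance assignment is excluded at a share under 0.05. For strain labels shuffled within stages, 1 of 21 arrangements, the real one, gave as many genes, with 77 the highest other against 1829, and 208 against 1037 for shifted genes. Shuffling only within the first 6 and within the last 14 strains of the sample numbering gave 1013 to 1273 genes with a strain effect, and none of those 20 shuffles reached 1829. The 10 splits of the repeats are too few for a share under 0.05. The real counts there were 1845, 1367, 607, 3014, 2665 and 1136, the highest other was 0, and 1 of the 10 splits gave as many each time.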

How the results depend on the processing

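Chosen only after seeing the data were the genes of each stage combined with a further change or used for the distance of N2, a floor of 5 thinned counts for the ratios of spread (for gene lists it was planned), single blocks of the sample numbering, libraries thinned for timing, the BCV without shallow libraries, and fits without reruns or without the 6 late libraries. The others were planned. Each cause below was not tested unless the setting itself shows it, through more or fewer genes or libraries. Counts of changed genes stayed within 1.5 times the reported ones with RLE scaling, DESeq2, strain as a block and fits without N2, shallow libraries, reruns or the 6 late libraries. The block changed no call of a list other than the epidermal one at 180 to 270 min and turned 2 list directions that did not pass, C-type lectins from 0 to 60 min (adjusted p = 0.999 with the block) and pharynx from 650 to 830 min (0.938). With no filter, which tests more genes, the counts were 3402, 4080, 1978, 5051, 5120 and 2881 in the 6 comparisons, and with the adjusted p only 1059, 1054, 688, 886, 977 and 565. The last 14 strains gave 253 genes from 0 to 60 min and 394 from 60 to 180 min. Of 1814 values of named genes in stage comparisons 1797 kept their call, 17 lost it and 0 turned. For strain effects 254 of 290 kept it, 35 lost it and 1 turned, MTCE.11 in strain 555, at -0.064 within the first 6 strains. In all 114 values of named genes could not be computed under an alternative. Depth limits these results to abundant genes.

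In the repeats no filter gave 2970, 2969, 1390, 5018, 4808 and 1873 genes. Leaving out each replicate in turn gave 1776 to 2090 from A to B, 1242 to 2183 from B to C (2183 without replicate 2), 627 to 939 from C to D (939 without replicate 2), 2855 to 3420 from D to E, 2465 to 3070 from E to F and 1109 to 1351 from F to G. Repeat numbers do not pair the libraries, as deviations of libraries with the same number correlated at -0.248 to 0.0270, and the number as a block gave 1881, 1359, 584, 2968, 2634 and 1078 genes.

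The strain effect was called for 4158 genes without a filter, 789 with limma-trend, 1.1e+02 (2.67% of 4200) within the first 6 strains and 265 (11.6% of 2285) within the last 14, and shifted genes numbered 7353, 1074 (of which 85 higher, against 651 of 1037), 105 and 109 in the same order. Camera passed 25 list tests with the preset correlation, 24 with the block and 3 with an estimated correlation. Lists outside the central 95% of variance numbered 3, 5 with a floor of 5 counts and 7 with tagwise dispersion. The SD of timing offsets of strains passed its test only with thinned libraries, at 10.5 min (p = 0.00465, against 0.0798 to 0.488 over the other settings).

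Strain spread depended on the measure and on the gene set. With 1 minus the Spearman correlation the log2 ratios were -0.83 at 0 min, -0.82 at 60 min, 0.57 at 180 min, 0.51 at 270 min, 0.32 at 440 min, -0.39 at 650 min and -0.55 at 830 min, all past the threshold (adjusted p from 7.0e-05 to 0.00611), and over the genes of each stage 0.12, 0.069, 0.36, 0.15, -0.017, -0.34 and -0.73. With the genes of each stage the root mean square gave -0.059 at 180 min, -0.16 at 270 min, -0.055 at 440 min, 0.47 at 650 min and -0.26 at 830 min. With the timing direction also removed these were -0.030, -0.14, -0.041, 0.39 and -0.24, without the 6 late libraries -0.044, -0.15, -0.030, 0.47 and -0.24, and in the last 14 strains -0.028, -0.19, -0.083, 0.44 and -0.24. Without thinning the ratio turned to 0.10 at 0 min, -0.020 at 180 min and 0.035 at 830 min, with a floor of 5 counts to 0.044 at 0 min, and without reruns to 0.021 at 650 min, none of which passed. On the BCV scale the ratios were -0.16 at 0 min, -0.095 at 180 min, 0.27 at 650 min and 0.0081 at 830 min. A floor of 30 thinned counts left 1 gene and could not be run.

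The BCV between strains rose with a CPM of at least 50 to 0.295, 0.319, 0.299, 0.314, 0.316, 0.418 and 0.350 over the 7 stages. With 10 counts in each stage it was 0.296 at 0 min, 0.288 at 60 min, 0.284 at 180 min and 0.296 at 650 min. Within the first 6 strains it was 0.185, 0.223, 0.242, 0.216, 0.206, 0.271 and 0.290 over the 7 stages. Within the last 14 it was 0.186, 0.229, 0.210, 0.212, 0.225, 0.263 and 0.239, or 0.227 at 440 min and 0.268 at 650 min without their late libraries with 0 min transcripts. The BCV of the repeats with each replicate left out ran from 0.0679 to 0.170 at A, 0.0688 to 0.208 at B, 0.106 to 0.169 at C, 0.0477 to 0.203 at D, 0.128 to 0.192 at E, 0.0914 to 0.248 at F and 0.0985 to 0.238 at G, with the lowest value without replicate 2 at A, B, D, F and G.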

Other observations

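The analyses of yolk and sperm transcripts, of other gene families and of explanations in this part were chosen only after the results were seen, except the list counts. Yolk protein (vitellogenin) transcripts, made in the adult gut, were present in embryo pools and unevenly so. Their summed level averaged 962 ± 1469 CPM (SD, n = 20) at 0 min, 1809 ± 1953 CPM at 60 min and 61.2 ± 106 CPM at 830 min in the strains, and 4046 ± 1486 CPM (n = 3) at A and 29.8 ± 28 CPM at G in the repeats. In the strains vit-3 had a log2 change of 0.74 ± 0.46 from 0 to 60 min and was not called. In the repeats none of 6 vitellogenins was called up to E, 5 rose from E to F, such as vit-1 (1.46 ± 0.37) and vit-3 (1.38 ± 0.38), and 6 fell from F to G, such as vit-3 (-6.88 ± 0.41) and vit-4 (-7.26 ± 0.46), as did the eggshell genes perm-2 (-5.20 ± 0.59) and perm-4 (-5.12 ± 0.59). The chitin synthase chs-2 rose from D to E (6.34 ± 0.36) and fell from E to F (-3.28 ± 0.28).

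Most members of families of low expression could be tested only without the filter on low counts, where single libraries hold few counts per gene. Histones rose in 50 and fell in 1 of 69 genes between 0 and 60 min, and fell in 52 and rose in 4 of 69 between 270 and 440 min, opposite in balance to the 3 rises and 1 fall in 5 with the filter and the 4 rises and 1 fall in 7 in the repeats. F-box A genes rose in 38 and fell in 2 of 123 between 440 and 650 min. Chemoreceptors, none of which passed the filter, rose in 22 and fell in 7 of 389 between 440 and 650 min, and in 3 and 7 of 497 between 650 and 830 min. Major sperm protein genes, which report adult sperm, passed the filter in 0 cases and had a median summed level of 0 CPM at each stage in the strains. Without the filter 5 of 24 rose and 0 fell between 270 and 440 min, when a single library, that of strain 564, held 247 CPM against a mean of 13.9 CPM over the 20. The MTCE genes had 1 rise in 12 between 60 and 180 min, MTCE.25 (1.03 ± 0.23, adjusted p = 4.77e-05 by edgeR), lost with no filter (0.95) and without the 8 rerun libraries (0.99).

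Strain profiles and mitochondrial transcripts followed the sample numbering. Profiles of strains next to each other in the numbering correlated with a mean r of 0.265 across genes, against -0.0473 over all pairs (one-sided permutation p = 1e-04, the smallest possible). The mean r was 0.425 within the first 6 strains, 0.0954 within the last 14 and -0.286 between them, so the step between both parts adds to it. Shuffling strain labels only within the first 6 and within the last 14 strains still gave at least 1013 genes with a strain effect (median 1130.5 of 20 draws, against 1829). Much of the strain effect thus lies in the step between both parts, a cut taken from these same data. The shuffle keeps that step whatever its cause. It therefore cannot tell a preparation or sequencing batch that follows the numbering from differences between the strains, and a batch stays open. Deeper libraries in the first 6 are argued against for the MTCE share. The slope of the share on library totals within stages and within both parts of the numbering gives a log2 step of 0.051 (95% jackknife interval -0.033 to 0.13), against 1.19 observed (0.88 to 1.49). Differences between the strains themselves stay open, as the repeats of strain 522 resembled strain 522 only at rank 6 of 20 (r = 0.204, against 0.527 for strain 536), and at rank 12 without the rerun libraries (r = 0.0786, against 0.315). Batch and strain cannot be told apart between the 6 and the 14, while within the first 6 the strain effect was called for 2.67% of 4200 genes and within the last 14 for 11.6% of 2285.

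The 6 late libraries with transcripts of 0 min form a further pattern. Slower development of the whole pool is argued against, because in 6 of 6 libraries the transcripts typical of 60 min (0.649% to 1.73% of their peak) and of 180 min (1.28% to 3.09%) stood below those of 0 min. Reads of the 0 min library of the same strain may be a source, as the 0 min transcripts deviated most like that library in 5 of the 6, with rank 11 in strain 564, while this held in 4 of 54 other late libraries. Embryos arrested at the 4-cell stage of the same strain would give the same resemblance, and a level up to 22.2% is possible for either, so they cannot be told apart.

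Neighbouring genes were shifted together in the same strain in 50 pairs, against a median of 30 in shuffled gene orders (highest 52, one-sided permutation p = 0.0025, 2000 shuffles), and paralogs such as pes-2.1 and pes-2.2 are among them. The first 6 strains of the sample numbering hold 46 of the pairs and 845 of the 1037 shifts, and 5 of their pairs include a 0 min transcript. Some genes were nearly absent in 1 strain, on few counts and without a test. In strain 516 grl-6 had 1 count against 31.2 expected (3.20%, where the lowest other strain had 33.3%). In strain 550 cyp-14A5 had 2 against 41.8 (4.79%, lowest other 17.98%), and in strain 575 idpp-12 had 1 against 42.7 (2.34%, lowest other 9.48%). The expected counts assume the nominal stage. Timing offsets at 650 min were -70.34 min in strain 516, -78.91 min in 550 and -20.44 min in 575. Whether pools behind their stage account for the low counts was not tested. Of 9 genes shifted in strain 522, 6 went in the same direction in its repeats, 2 of them by at least 2-fold. Shifts of some other strains went with the 522 repeats as often, 9 of 12 in strain 566 and 6 of 9 in 573. In strain 529 it was 12 of 42 and in 502 it was 0 of 13. In strain 536, 2 of 3 went along by at least 2-fold. The count of 6 of 9 is thus not particular to strain 522. Among the 9, nlp-40 had a log2 shift of 1.41 and 1.41 in its repeats, and homt-1 of -2.40 and -1.83, while ZC204.14 had 1.64 and -2.30. These genes were named after their values were seen.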
